A study of Homo sapiens with 9 samples.

How the data were processed

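Total RNA of Kasumi-1 cells was labelled with biotin by a whole-transcript sense-strand assay and hybridised to Affymetrix arrays, per the labels' protocols. There were 3 groups of 3 arrays, and each array was placed in its group by its title. The labels call the arrays of a group technical replicates. The cells of the untreated and the dasatinib-treated group were taken after 12 weeks and those of the withdrawal group after 13 weeks, per the series' design text. No scan date or other batch was given in the sources used here, so no batch term was fitted.

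The deposited table holds 1 value for each of 33297 transcript clusters on each of the 9 arrays. The submitters' processing notes name Affymetrix Expression Console. Its version, the summarisation algorithm, the background correction and the annotation release were not given in the sources used here. The deposited values were read as log2 expression because they run from 1.70 to 13.6, and no header states the log base. Array medians lay between 4.97 and 5.01, so the authors' values were taken as already normalised between arrays. An array has no read depth, and the number of arrays limits the precision. A transcript cluster at the low end of the scale has values close to background, where fold changes are compressed.

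Transcript clusters were named through the platform annotation. Of the 33297 clusters, 19460 named 1 gene, 1754 named several and 12083 named none. Clusters naming several genes or none were not used for named results. Entrez identifiers of 19429 clusters matched the human RefSeq gene table of assembly GRCh38, 31 did not, and 0 symbols needed an update. A gene was represented by the cluster with the highest mean over the 9 arrays, which left 18417 genes. Of 769 genes with several clusters, 1 had clusters whose group means differed at least 1.5-fold in opposite directions between the withdrawal group and untreated cells. Gene starts in that table served only to order genes along chromosomes in a test of chromosome shifts, no coordinate is printed, and 23 genes are not reported here.

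Differences were tested with limma 3.58.1 in R 4.3.3 as 1 linear model over the 9 arrays with empirical Bayes moderation (6 residual and 3.5 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 together with a change of at least 1.5-fold. All adjusted p-values of genes come from this limma model, and errors of log2 changes are its standard errors. A moderated F test asked for any difference among the 3 groups. Fixed lists of genes, 43 in number with 1077 symbol entries of which 979 were measured, were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and limma's fry were alternatives. With an estimated correlation, limma's camera uses the 6 residual degrees of freedom. Its p-values can therefore rise even where the estimate lies below 0.01. The comparisons, thresholds, gene lists, other settings to try and the rule for naming genes were set before the data were examined. That rule takes per comparison the 8 largest rises and 8 largest falls whose arrays do not overlap between groups, the 4 members of each described list with the largest change, 7 kinases inhibited by dasatinib, RUNX1 and RUNX1T1, the 4 largest changes of each reversal class, and the 4 largest each way of the genes changed against both other groups. Where a list has 5 or fewer called members, the remaining ones were named after their values were seen.

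Genes called between treated and untreated cells were classed by the calls of the other comparisons as returned, part returned, kept, overshot or between. The class of genes that moved further in the same direction was split from the last of these after the data were seen. The chance level of agreement between comparisons that share arrays was simulated 100 times with unchanged groups. After the withdrawal group was seen to differ so widely, the share of its signal in each treated array was fitted on the linear scale over 133 genes at least 8-fold higher in it than in untreated cells. That share was then subtracted from each treated array as an added alternative, with 623 values set to a floor. A further added alternative subtracted the upper quartile of the shares of single genes, 6.3%, from each treated array.

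The pipeline was tested on simulated data for 18417 genes in the comparison of treated with untreated cells. Of 50 genes simulated at each fold size, 27 were recovered at 1.5-fold, 50 at 2-fold, 50 at 4-fold and 50 at 8-fold, with 0 false calls. Without the fold minimum, 48 of the 1.5-fold genes were recovered with 5 false calls. A simulated share of 6% was recovered as 6.01%. When the hypoxia list was lowered, camera called 2 lists, that one and the glycolysis list, of which 3 of 21 members had been lowered with it. Alternatives covered normalisation, median centring, a filter on dim genes, the fold minimum, a test against a 1.2-fold change, trended and robust moderation, the arrays in the fit, a replicate block, the transcript clusters tested and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.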

Results

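Gene expression was measured in Kasumi-1, a human acute myeloid leukaemia line that carries the RUNX1-RUNX1T1 fusion gene and a mutated KIT receptor. Dasatinib inhibits tyrosine kinases of the ABL and SRC families and KIT. Untreated cells (K) were set beside cells kept in dasatinib for 12 weeks at doses of 12, 24 and finally 48 nM (R48) and cells taken 1 week after the drug was withdrawn (PR48). The series describes the drug-treated state as resistant and reversible, so the comparisons ask what changed under the drug and what went back after it. Each group had 3 arrays. They are technical replicates per the labels, so p-values measure at most technical spread and not the spread between cultures.

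Arrays of the same group were close to one another, with Pearson correlations across transcript clusters of 0.995 to 0.997. Clusters are not independent replicates, and these correlations only describe the arrays. K and R48 arrays correlated at 0.992 to 0.994. The arrays labelled PR48 stood apart, at 0.956 to 0.957 with K and 0.962 to 0.964 with R48. The first principal component held 89.8% of the variance and separated the arrays labelled PR48 from the 6 others, and the second held 5% and separated K from R48. Within groups the median SD of a gene was 0.06 in K, 0.06 in R48 and 0.07 in PR48 on the log2 scale. The limma F test found a difference among the 3 groups in 8876 of 18417 genes (48.2%).

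The fusion gene marks this cell line, and its RUNX1T1 part was read by the array. RUNX1T1 stood at 8.84 ± 0.07 in K and 8.70 ± 0.04 in R48 (log2, mean ± SD, n = 3), and at 4.98 ± 0.05 in the arrays labelled PR48. RUNX1, whose promoter drives the fusion, stood at 9.22 ± 0.03, 9.11 ± 0.01 and 8.84 ± 0.02. CD34, a surface marker of blood progenitors, went from 8.85 ± 0.02 in K and 8.53 ± 0.03 in R48 to 4.81 ± 0.19 in PR48. LYZ, which encodes lysozyme, rose from 4.09 ± 0.03 in K to 7.81 ± 0.01 in R48 and 11.71 ± 0.05 in PR48. The receptor gene FLT3 and the homeobox gene MEIS1 followed the order of LYZ. R48 replicates 2 and 3 had identical deposited values for LYZ (7.8083), FLT3 (6.9662) and MEIS1 (5.2527). Replicates 1 and 2 did for RUNX1T1 (8.6736), and replicates 1 and 3 for RUNX1 (9.1079) and IRF8 (7.9536). The peroxidase gene MPO was equal in all 3 R48 arrays (11.8966). CD34 had no such tie in R48, and K and PR48 had none in these genes. Why values are equal was not tested. Where they are, the R48 SD and the p-values may understate technical spread.

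**Figure D1:**
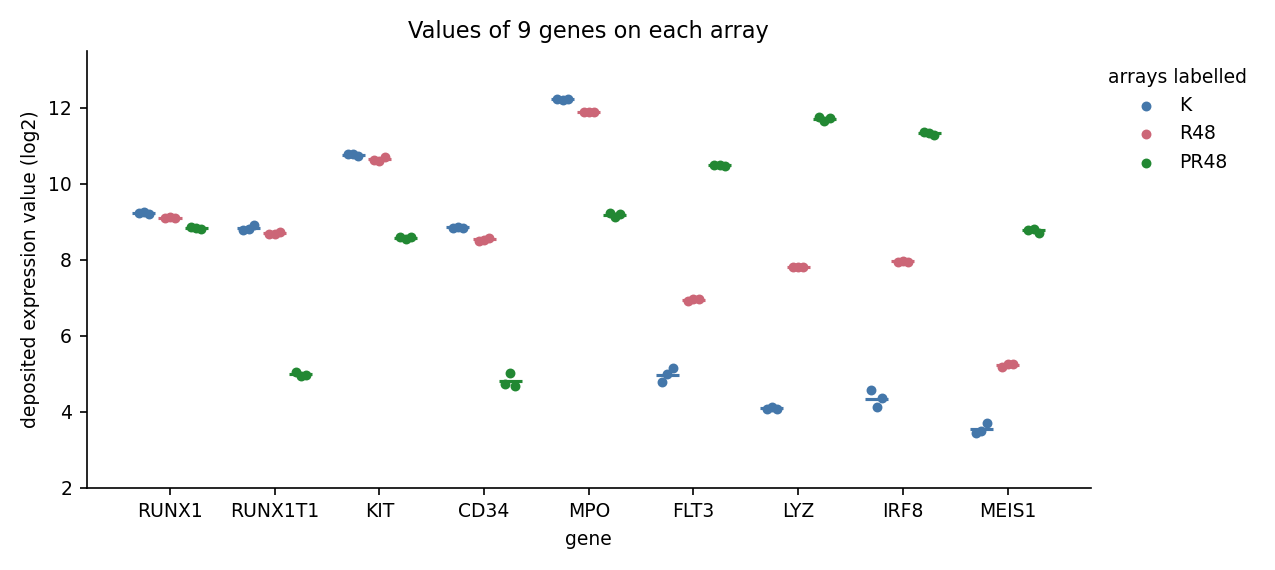
Deposited log2 expression values of 9 genes (y axis) on each of the 9 arrays, grouped by gene along the x axis. Points are arrays and bars are group means (n = 3). RUNX1T1 and CD34 are near 5 in the arrays labelled PR48 and above 8 in K and R48, while LYZ, IRF8, FLT3 and MEIS1 are lowest in K, intermediate in R48 and highest in PR48.

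Under continuous dasatinib, genes of the response to low oxygen fell as a list, with 7 of 24 measured members called lower (camera adjusted p = 2.10e-12), and some genes that are nearly silent in K rose. BNIP3, a mitochondrial protein induced by hypoxia, fell by 1.75 ± 0.06 (log2 ± SE). ALDOC, a glycolytic aldolase, fell by 1.99 ± 0.05, from 7.80 in K to 5.81 ± 0.07 in R48. LYZ rose 13.2-fold (log2 3.73 ± 0.04, from 4.09 ± 0.03 to 7.81 ± 0.01, adjusted p = 6.7e-11). Its value was identical in R48 replicates 2 and 3, so this R48 SD, the SE and the p-value may understate technical spread. The transcription factor IRF8, which directs monocyte development, rose 12.2-fold (log2 3.61 ± 0.09), with the same limit, as R48 replicates 1 and 3 were identical. ITGAL, an integrin chain of leukocytes, rose 9.58-fold (log2 3.26). These 3 genes were higher still in the arrays labelled PR48, and with a fitted share of the PR48 signal subtracted from the R48 arrays they stood at 2.24, 2.80 and 2.61, and 77 genes were called higher in place of 143. The share that LYZ alone would need is 6.25%, so its value after subtraction depends on the share chosen. With 6.3%, the upper quartile of the shares of single genes, LYZ stood at -0.003 and was not called. IRF8 (2.21) and ITGAL (2.20) were still called, but alone they would need 8.98% and 10.3%. Taking off less than that leaves them higher by construction.

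In all, 320 of 18417 genes were called between R48 and K, 143 higher and 177 lower in R48. Among the largest rises were also TARP, from the T cell receptor gamma locus (3.83 ± 0.15), the secreted integrin ligand EDIL3 (3.45 ± 0.14), the choline transporter SLC44A1 (3.42 ± 0.11), BEX1 (3.07 ± 0.07) and LAMP5 (2.94 ± 0.07). Among the largest falls, besides that of ALDOC, were those of GXYLT2 (-2.29 ± 0.15), the interleukin 18 receptor subunit IL18RAP (-2.29 ± 0.07), the laminin chain LAMB1 (-2.28 ± 0.10), the RNA-binding protein KHDRBS3 (-2.13 ± 0.08), PGAP1 (-2.06 ± 0.11) and the adhesion molecule EPCAM (-1.86 ± 0.33). Of the 7 large rises of at least 8-fold, all but EDIL3 were in genes that were higher still in the arrays labelled PR48. No fall reached 8-fold. On the adjusted p alone, 2340 genes passed.

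Of the 24 hypoxia genes 7 were lower and 0 higher, with a median of -0.42. The call of the list held with an estimated correlation (adjusted p = 0.00684). That correlation is estimated between technical replicates, so it covers array noise and not how these genes vary together between cultures. The members with the largest falls were BNIP3 (-1.75), PFKFB4, an enzyme that sets glycolytic flux (-1.52), the mTOR inhibitor DDIT4 (-1.50) and the collagen hydroxylase P4HA2 (-1.01). Of 21 glycolysis genes 5 were lower and 0 higher: ALDOC, PFKFB4, the phosphofructokinase PFKP (-1.09), the enolase ENO2 (-0.78) and PFKFB3 (-0.59). The glycolysis call had adjusted p = 2.71e-11 but adjusted p = 0.146 with an estimated correlation.

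The lists of the ATF4 amino acid response and of cholesterol synthesis had a camera adjusted p of 8.68e-08 and 5.04e-05, both downwards, against adjusted p = 0.146 and adjusted p = 0.157 with an estimated correlation. Of 38 genes of the ATF4 amino acid response 4 were lower: DDIT4, the folate enzyme ALDH1L2 (-1.38), the secreted hormone STC2 (-0.86) and the stress factor DDIT3 (-0.68). DDIT4 and STC2 also belong to the hypoxia list. Of 19 cholesterol synthesis genes 4 were lower, namely MSMO1 (-0.82), INSIG1 (-0.71), STARD4 (-0.63) and HMGCS1 (-0.61). Chaperones of the endoplasmic reticulum fell as a list by a median of 0.21 with 0 of 21 members called, and ribosomal protein genes by a median of 0.07 with 0 of 35 called (adjusted p = 1.41e-07 and 0.00018, against adjusted p = 0.146 and adjusted p = 0.196 with an estimated correlation). The HMGCS1 call was lost without K replicate 3 (-0.58) and with each array centred on its median (-0.58).

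Of 36 adhesion and migration genes 6 were called higher and 0 lower (camera adjusted p = 0.000186, against adjusted p = 0.146 with an estimated correlation). ITGAL (3.26), the galectin LGALS1 (1.46), the calcium-binding S100A10 (1.27) and the chemokine receptor CXCR4 (0.69) led it. Of 26 monocyte and macrophage genes 4 were higher, IRF8, the chemokine receptor CCR2 (1.83), MS4A6A (1.45) and the lysosomal glycoprotein CD68 (0.65), and 0 were lower (camera adjusted p = 0.00104, against adjusted p = 0.136 with an estimated correlation). All of these named genes were higher again in the arrays labelled PR48, and a fit over 133 genes at least 8-fold higher in PR48 than in K put 4.36%, 4.33% and 4.59% of the PR48 signal in R48 replicates 1, 2 and 3. The shares of the single genes had quartiles of 2.9% and 6.3%. With the share of each array subtracted, MS4A6A stood at 0.07, CD68 at 0.17, S100A10 at 0.24 and CXCR4 at 0.18 and lost their calls, while IRF8 (2.80), ITGAL (2.61), CCR2 (0.99) and LGALS1 (0.71) kept them, and both lists had adjusted p = 0.0588. With 6.3% subtracted, close to the shares that CCR2 (7.03%) and LGALS1 (6.82%) alone would need, these stood at 0.38 and 0.21 and were not called. At that setting the monocyte list had a camera adjusted p of 0.522 and the adhesion list 0.828. Without K replicate 3 CD68 stood at 0.55 and was not called.

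Lists of mitosis, DNA replication and oxidative phosphorylation were called upwards by small amounts. With an estimated correlation they had adjusted p = 0.373, adjusted p = 0.484 and adjusted p = 0.315. Mitosis genes had a median of 0.09 and 0 of 32 members called (camera adjusted p = 0.000858), with PLK1 at 0.50. DNA replication genes had a median of 0.05 and 0 of 33 called (adjusted p = 0.0258), and oxidative phosphorylation genes a median of 0.09 with 1 of 36 called, COX7B (0.67, adjusted p of the list = 0.000216). The DNA replication call was lost without K replicate 1 (adjusted p = 0.0781) and without R48 replicate 3 (adjusted p = 0.117), and among genes above the median level (adjusted p = 0.0711).

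**Figure D2:**
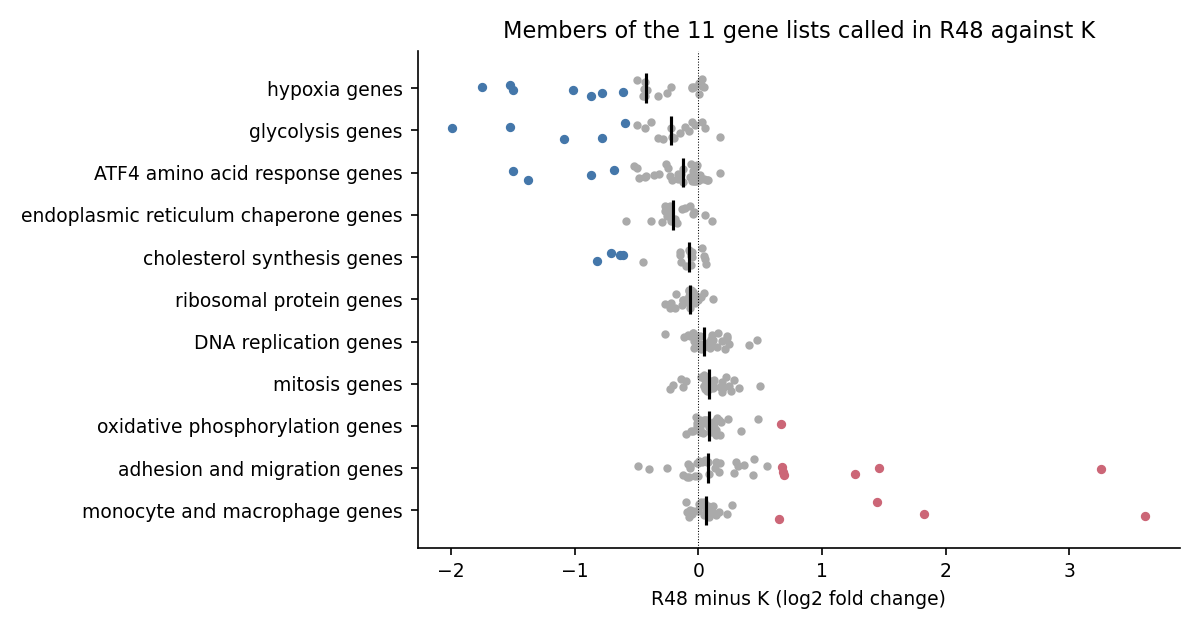
Log2 fold change of R48 minus K (x axis) for each measured member of the 11 gene lists called in that comparison (y axis). Each point is a gene, blue if called lower, red if called higher and grey if not called, and the black bar is the list median, -0.42 for hypoxia genes and 0.06 for monocyte and macrophage genes.

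The main kinases that dasatinib inhibits were measured in both groups. LYN, a SRC family kinase of blood cells, was 1.51-fold higher in R48 (log2 0.59 ± 0.06). KIT stood at -0.13, SRC at -0.03, FYN at 0.13, YES1 at 0.29, ABL1 at 0.02 and ABL2 at -0.24, none of them called. RUNX1 (-0.11) and RUNX1T1 (-0.14) were not called either. Among 24 measured dasatinib targets LYN was the 1 gene called, and the list was not called (adjusted p = 0.116). The LYN call rested on the fold minimum and was lost without K replicate 2 (0.55) and without R48 replicate 3 (0.56).

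Of the 43 lists, 11 were called between R48 and K, 5 up and 6 down, and 1 of these, hypoxia, held with an estimated correlation. The estimate was -1e-04 for hypoxia genes and -0.0176 for monocyte and macrophage genes, below the preset 0.01. A higher correlation is therefore not why the p-values of these lists rose. Counts of called members were the same when p-values were adjusted over the list alone. With the PR48 share subtracted, an alternative added after the data were seen, 288 genes were called, 77 higher and 211 lower. Of the 143 genes higher in R48, 75 kept their call after subtraction and 68 lost it, and of the 177 lower genes 169 kept it. With the upper quartile of 6.3% subtracted, 61 of the 143 kept it, among them EDIL3 (3.54), TARP (2.09) and SLC44A1 (1.76). TARP and SLC44A1 alone would each need 8.14%, more than was taken off. Both shares were taken from genes that are higher in PR48. Loss and survival of calls among such genes therefore follow in part from the choice of the share.

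The change from R48 to PR48 was far wider than that under the drug. CD69, an early activation marker of lymphocytes, fell by 5.16 ± 0.10 (35.8-fold, adjusted p = 1.13e-10). The growth factor HGF fell by 5.08 ± 0.08 and RHEX, a regulator of erythroid expansion, by 4.98 ± 0.07. CTSG, the granule protease cathepsin G, rose 16.9-fold (log2 4.08 ± 0.07), and HORMAD1, a meiotic chromosome protein, rose 21.2-fold (4.41 ± 0.06). RUNX1T1 fell by 3.71 ± 0.05 in the same arrays, ERG by 4.13 ± 0.05 and CD34 by 3.72 ± 0.08.

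In total 3498 genes (19%) were called, 1621 higher and 1877 lower in PR48, and 95 rises and 105 falls were at least 8-fold. Further large rises were those of ZNF626 (4.40 ± 0.19), WDR49 (4.14 ± 0.05), the tryptophan-degrading enzyme KYNU (4.07 ± 0.06), the transcription factor TFEC (4.04 ± 0.11), SERPINB8 (3.96 ± 0.08) and LY86 (3.94 ± 0.10). Further large falls were those of the Wnt co-receptor LRP6 (-4.57 ± 0.07), GTSF1 (-4.56 ± 0.10), MCTP2 (-4.51 ± 0.18), ITM2A (-4.44 ± 0.12) and the glutamine transporter SLC38A1 (-4.43 ± 0.10).

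The azurophil granule, monocyte and macrophage, and lysosome lists were called upwards in the arrays labelled PR48. The camera adjusted p-values were 0.00232, 0.00232 and 0.0353, against adjusted p = 0.264, adjusted p = 0.119 and adjusted p = 0.753 with an estimated correlation. Of 19 azurophil granule genes 10 were higher, among them CTSG (4.08), MS4A3 (3.91), LYZ (3.89) and the ribonuclease RNASE2 (3.22), and 3 were lower, the peroxidase MPO (-2.71), the transcription factor CEBPE (-1.80) and GFI1 (-0.74). Of 26 monocyte and macrophage genes 6 were higher and 0 lower, led by MS4A6A (3.83), CCR2 (3.39), IRF8 (3.37) and CD68 (2.83). Of 27 lysosome genes 11 were higher and 2 lower, with the protease CTSS (2.30), GRN (1.64), the peptidase TPP1 (1.63) and NPC2 (1.44) at the head, and GAA (-1.38) and PSAP (-0.77) lower. The late neutrophil list, with 3 of 20 higher and 2 lower, and the mast cell and basophil list, with 2 of 21 higher and 5 lower, were not called (adjusted p = 0.567 for each). RUNX1T1 was lower than in R48 by 3.71 log2 units in these arrays (-3.71).

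Lists of p53 targets, the cytoskeleton and type I interferon were also called upwards. Their camera adjusted p-values were 0.0318, 0.00387 and 0.0365, against adjusted p = 0.196, adjusted p = 0.119 and adjusted p = 0.196 with an estimated correlation. Of 24 p53 targets 10 were higher, led by the death receptor TNFRSF10B (2.41), the ribonucleotide reductase subunit RRM2B (1.99), RPS27L (1.74) and the repair factor DDB2 (1.56), and 4 were lower, TP53INP1 (-1.14), GADD45A (-0.96), TP53I3 (-0.94) and SESN2 (-0.61). Of 26 cytoskeleton genes 8 were higher and 0 lower, led by MYL12A (1.54), ACTN1 (1.33), CORO1A (1.21) and TAGLN2 (1.06). Of 34 type I interferon genes 7 were higher, led by TRIM22 (3.22), SAMD9 (2.34), XAF1 (1.92) and BST2 (1.53), and PARP9 (-1.04) was lower. The interferon call was lost without PR48 replicate 2 (adjusted p = 0.054). RUNX1T1 and CD34 were lower by over 3 log2 units in the same arrays.

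Heat shock, mitosis, chromatin and histone lists were called downwards. The camera adjusted p-values were 0.000541, 0.00115, 0.00115 and 0.0365, against adjusted p = 0.261, adjusted p = 0.59, adjusted p = 0.119 and adjusted p = 0.602 with an estimated correlation. Of 16 heat shock genes 5 were lower, HSPB1 (-1.57), HSPA4L (-1.40), the HSP90 cochaperone FKBP4 (-1.40), CHORDC1 (-0.80) and BAG3 (-0.76). Of 32 mitosis genes 7 were lower, led by the kinase CDK1 (-1.12), CENPE (-0.83), KIF20A (-0.75) and FOXM1 (-0.74). Of 25 polycomb and chromatin regulators 10 were lower, led by the DNA demethylating enzyme TET1 (-3.20), KDM5B (-1.58), CBX2 (-1.56) and JARID2 (-0.83). Of 22 histone genes 1 was lower, H3-3B (-0.76). The histone call was lost without R48 replicate 3 (adjusted p = 0.0663), PR48 replicate 2 (adjusted p = 0.0754) or PR48 replicate 3 (adjusted p = 0.0646), and among genes above the median level (adjusted p = 0.275).

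Among dasatinib targets, KIT fell by 2.06 ± 0.04, ABL2 by 1.05 ± 0.08, LYN by 1.02 ± 0.06 and YES1 by 0.84 ± 0.05, and SIK2 (-0.67) and EPHB4 (-0.62) were lower too. CSF1R, the receptor of macrophage colony-stimulating factor, rose by 1.70 ± 0.07 and the kinase TEC by 1.15 ± 0.05. RUNX1 was at -0.27 and not called. The target list went both ways and was not called (adjusted p = 0.587). Of the 43 lists 10 were called, 6 up and 4 down, and 0 of them held with an estimated correlation. Adjusted over the list alone, the counts of called members were the same, except that EPCAM was not called in its list.

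Against untreated cells, the arrays labelled PR48 differed in 3796 genes (20.6%), 1703 higher and 2093 lower. LYZ was 197-fold higher (log2 7.62 ± 0.04, adjusted p = 7.78e-14) and IRF8 126-fold higher (6.98 ± 0.09). FLT3, a receptor of early myeloid and lymphoid cells, rose from 4.98 ± 0.18 to 10.49 ± 0.01 (mean ± SD, n = 3), and MEIS1 rose by 5.23 ± 0.07. RUNX1T1 was 14.5-fold lower (log2 -3.85 ± 0.05), CD34 16.4-fold lower (-4.04 ± 0.08) and KIT 4.55-fold lower (-2.19 ± 0.04).

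TARP (7.36 ± 0.15), SLC44A1 (6.91 ± 0.11), HORMAD1 (6.65 ± 0.06), ITGAL (6.40 ± 0.08), LAMP5 (6.35 ± 0.07) and BEX1 (6.16 ± 0.07) were the other large rises. CD69 (-5.07 ± 0.10), RHEX (-4.89 ± 0.07), RHOBTB3 (-4.68 ± 0.10), LRP6 (-4.66 ± 0.07), GTSF1 (-4.52 ± 0.10), SLC38A1 (-4.44 ± 0.10), CLGN (-4.33 ± 0.06) and ZNF711 (-4.33 ± 0.09) were the large falls. At least 8-fold rises numbered 133 and falls of that size 122. LYN (-0.43), RUNX1 (-0.38) and YES1 were not called, and ABL2 fell by 1.29 ± 0.08.

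Apart from hypoxia genes, each list called here was also called between PR48 and R48, and both comparisons share the PR48 arrays. The monocyte, cytoskeleton, p53 target and lysosome lists were called upwards with camera adjusted p-values of 0.0016, 0.0018, 0.0147 and 0.029, against adjusted p = 0.0823, adjusted p = 0.0823, adjusted p = 0.142 and adjusted p = 0.573 with an estimated correlation. Of 26 monocyte and macrophage genes 7 were higher, led by IRF8, MS4A6A (5.28), CCR2 (5.22) and CD68 (3.48). Of 26 cytoskeleton genes 7 were higher, led by MYL12A (2.09), CORO1A (1.51) and CNN2 (1.21), and CCN1 (-0.62) was lower. Of 24 p53 targets 10 were higher, led by RRM2B (2.51) and TNFRSF10B (2.20), and 4 lower, led by GADD45A (-1.16) and TP53INP1 (-1.05). Of 27 lysosome genes 12 were higher, led by CTSS (2.30) and TPP1 (1.79), and 2 lower, GAA (-1.70) and PSAP (-1.06). RUNX1T1 and CD34 were each lower by about 4 log2 units in these arrays.

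The heat shock, chromatin, mitosis, hypoxia and histone lists were called downwards with camera adjusted p-values of 0.0016, 0.0018, 0.023, 0.023 and 0.0442, against adjusted p = 0.315, adjusted p = 0.0823, adjusted p = 0.612, adjusted p = 0.147 and adjusted p = 0.573 with an estimated correlation. Heat shock genes had 5 of 16 members lower, led by HSPA4L (-1.75) and HSPB1 (-1.60), and polycomb and chromatin regulators 10 of 25, led by TET1 (-3.55) and CBX2 (-1.85), with KAT2A (0.72) higher. Mitosis genes had 6 of 32 lower, led by CDK1 (-0.79), and 2 higher, NUSAP1 (0.80) and PLK1 (0.70). Of 24 hypoxia genes 7 were lower, led by BNIP3 (-2.22), STC2 (-2.21) and P4HA2 (-1.72), and 2 higher, NDRG1 (1.98) and BHLHE40 (1.18). Of 22 histone genes H3-3B (-0.69) was lower and H2BC12 (1.03) higher. The histone call was lost when K replicate 1, K replicate 3, PR48 replicate 2 or PR48 replicate 3 was left out (adjusted p = 0.0534, 0.0542, 0.0647 and 0.0608). Among genes above the median level the mitosis, hypoxia and histone calls were lost (adjusted p = 0.197, 0.161 and 0.283). In total 9 lists were called, 4 up and 5 down, and counts were the same adjusted over the list alone.

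The question whether changes under the drug went back was put to the 320 genes called between R48 and K, set against the arrays labelled PR48. RUNX1T1 (-3.85) and CD34 (-4.04) were lower in those arrays than in K, and the classes compare arrays by their labels. A minority of genes were back near K. EDIL3 rose to 7.07 ± 0.20 under the drug and was at 3.08 ± 0.26 in PR48, and ALDOC and PFKFB4 of the glycolysis list came back to within 1.5-fold of K. PTPRM, a receptor phosphatase, returned as well. In all 34 genes (10.6%) were classed as returned, 12 that had risen and 22 that had fallen, and 2 as part returned, RAB31 and GXYLT2.

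More of the 320 genes kept their change or moved on in the same direction. IL18RAP, BNIP3, FSTL1 and DDIT4 were among 64 genes (20%) that kept it. TARP, LYZ, IRF8 and SLC44A1 were among 162 genes (50.6%) that moved further from K. Of the 162, 99 had risen in R48, and 68 of these 99 lost their call between R48 and K with the PR48 share subtracted. PR48 signal in the R48 arrays would by itself put rising genes in this class. NPR3, the growth factor ANGPT1, the amine transporter SLC18A2 and AIG1 were among 38 (11.9%) that passed beyond K in the opposite direction. NPR3 was at 6.28 in K, 7.84 ± 0.02 in R48 and 3.70 ± 0.15 in PR48. TNFAIP3, ENO2, ZNF610 and MAP3K21 were among 20 genes in none of these classes.

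The median fraction of the change against K that remained in PR48 was 1.70 (quartiles 0.433 and 3.14), and 1.10 over all transcript clusters. Over the 320 genes it was 3.02 for genes higher in R48 and 1.28 for genes lower in R48. A small share of the PR48 signal in R48 would by itself make this fraction large for rising genes. Of the 143 genes higher in R48, 68 lost their call with the share subtracted, so 3.02 is no measure of persistence after withdrawal. Between R48 and K and between PR48 and K, 105 rising genes and 123 falling genes were shared, where independent lists of these sizes would share 13.2 and 20.1. Simulated unchanged groups measured against the same K arrays gave 0.01 calls between R48 and K on average, too few to set a level for shared calls. Across genes, which are not independent replicates, the covariance of the 2 sets of changes was 0.0723, against 0.00273 in simulation, and their correlation was 0.456 against 0.5. The simulated covariance already covers array noise that is shared through K. The 3 K arrays are too few to split, so anything else the shared controls add was not measured. A share of the PR48 signal in the R48 arrays would also add to the excess.

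**Figure D3:**
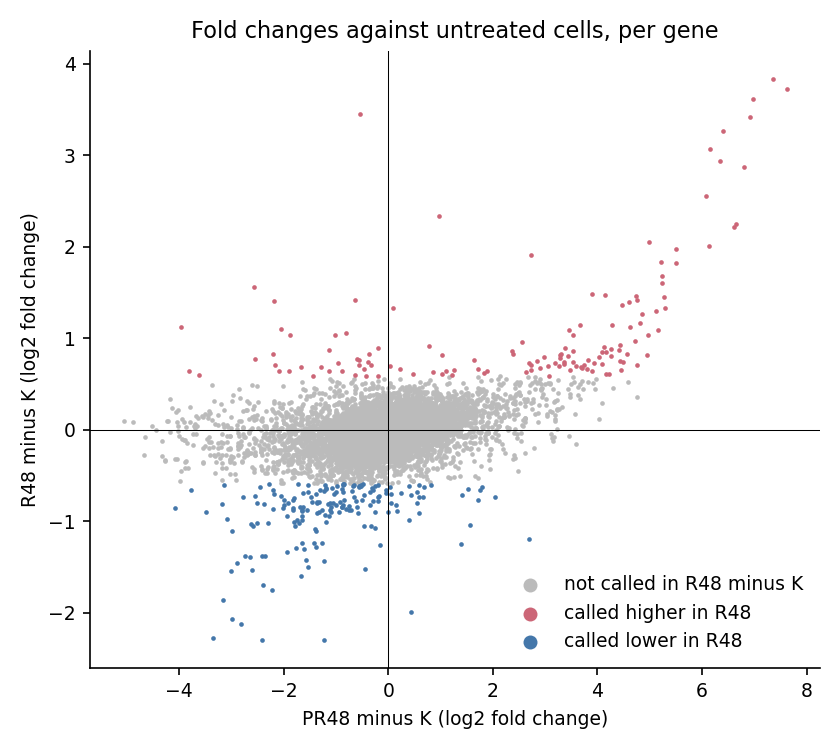
Log2 fold change of R48 minus K (y axis) against that of PR48 minus K (x axis), 1 point per gene. Of the 320 called genes, 143 are higher (red) and 177 lower (blue) in R48, grey points were not called, and the genes that rose in R48 by over 2.5 log2 units also lie far to the right, with EDIL3 at the left as the exception.

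A further 2911 genes differed in PR48 from both other groups in the same direction without being called between R48 and K, 1311 higher and 1600 lower. ZNF626, CTSG, MS4A3 and the phosphatase PTPN12 had the largest rises among them. PTPN12 stood at 2.95 ± 0.03 in K, 3.41 ± 0.08 in R48 and 7.24 ± 0.15 in PR48. CD69, RHEX, LRP6 and GTSF1 had the largest falls, and CD69 stood at 9.36 ± 0.03, 9.46 ± 0.05 and 4.30 ± 0.23. RUNX1T1 and CD34 were likewise lower in PR48 than in both other groups.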

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

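The tests of a hybridisation batch, of another differentiation state, of exchanged labels and of smaller regulation in all cells and both subtractions of the PR48 share were chosen only after the results were seen. Transcript clusters that name no gene, 12083 in number, were left out of the comparisons. Of these, 57 were called higher in R48 than in K and 146 lower, 1.7% in all, beside 1.7% of the genes tested. Between PR48 and K, 485 of these unnamed clusters were called higher and 756 lower, 10.3% in all, beside 20.6% of the genes tested. The limma F test found 8876 genes, and of 100 drawn splits of the 9 arrays 1, the real one, gave as many. Such a count is rare under a random assignment of the arrays. As these are technical replicates, it says nothing of differences between cultures. The highest other split gave 7525 genes, and the 4 other drawn splits that kept the PR48 arrays together gave at least 7262 while those that parted them gave at most 51, so the count mainly follows the PR48 arrays. With 6 arrays, the real splits gave 318 genes for R48 against K, 3498 for PR48 against R48 and 3796 for PR48 against K, each the 1 of 10 splits with as many. The highest other split gave 0 genes in each, and 10 splits are too few for a share under 0.05.

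The arrays labelled PR48 have far lower RUNX1T1 and CD34 than the others and carry LYZ, IRF8, FLT3 and MEIS1 at high levels. A hybridisation batch of its own as the whole cause would leave R48 at the level of K, but in 87.2% of the 133 genes at least 8-fold higher in PR48 all 3 R48 arrays lay above all 3 K arrays, against at most 11.7% in 100 simulations that chose genes the same way with R48 unchanged from K. The same cells in another differentiation state would keep the fusion under the RUNX1 promoter, but RUNX1T1 fell by 3.47 log2 units more than RUNX1 (-3.47 for the difference). That test reuses the low RUNX1T1 that set these arrays apart, so it is not independent of the observation. A candidate explanation that stays open is cells of another origin. Per-chromosome medians of the change from K spread by 0.156, against 0.0583 at most in 10000 shuffles (permutation p = 1e-04, the smallest these can give). R48 against K gave the same p, with a spread of 0.0669 against 0.0171 at most. The test therefore does not single out the PR48 arrays and cannot decide their origin. Whether the R48 and PR48 labels were exchanged cannot be told apart here, since the ERK output list moved both ways (adjusted p = 0.958), and a subclone that lost the fusion was not tested.

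Genes high in PR48 and nearly silent in K rose in R48, and over 634 genes that differ at least 4-fold between PR48 and K, adding 5.05% of the PR48 signal to K left 0.583 times the squared error of scaling all log2 changes by 1 fraction (bootstrap interval 0.471 to 0.725). The same regulation at a smaller size in all cells would move the falling genes too, but they had gone only 0.156 times as far along their change as the rising ones (interval 0.0637 to 0.283). This ratio compares medians and assumes equal fractions up and down. Both intervals come from resampling genes, which are not independent replicates, so they measure no spread between arrays or cultures. Of 122 genes at least 8-fold lower in PR48, all R48 arrays lay below all K arrays in 57 and above them in 28. The shares of these 122 genes had quartiles of -6.4% and 21.6%, so 1 small share does not describe them either. The PR48 share predicts 0.029 times the fall of the hypoxia list, so it does not account for that list. A small share of PR48-type cells or RNA in the R48 samples may therefore be the source of part of these rises, while calls lost on subtracting a share taken from such genes are no evidence for it. With the upper quartile of the shares of single genes (6.3%) subtracted 61 of the 143 rises kept their call, such as IRF8 (2.21), ITGAL (2.20) and TARP (2.09). Alone these would need 8.98%, 10.3% and 8.14%, so a call kept at 6.3% is no evidence of a rise apart from the share. Why the shares of single genes differ stays open. Whether cells before harvest or RNA after it were mixed was not tested.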

How the results depend on the processing

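The 2 subtractions of the PR48 share were chosen only after the result was seen, and the other settings were chosen before. With the upper quartile of that share subtracted, R48 against K changed sign in LYZ (-0.003), MS4A6A (-1.40), CD68 (-0.11), MEIS1 (-0.14), S100A10 (-0.63) and CXCR4 (-0.13), which follows from taking off more than these genes rose. No other result reversed. Without a fold minimum the calls were 2340 (R48 against K), 8249 (PR48 against R48) and 8684 (PR48 against K), with 223 returned genes and 5629 changed against both other groups; at 2-fold they were 97, 1736, 1905, 8 and 1508, which follows from the threshold itself. With genes above the median level alone, R48 against K had 197 calls (106 higher, 91 lower), as fewer genes were tested. Over all transcript clusters it had 572 calls and 88 returned, and the remaining fraction was 1.10. The estimated correlation left 1, 0 and 0 gene lists of the 3 comparisons, and fry, which tests each list without comparing it with other genes, gave 28, 38 and 40.

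Leaving out each array in turn gave 318 to 337, 3448 to 3547 and 3756 to 3830 calls, 8368 to 8642 genes by the F test, 31 to 39 returned genes, a remaining fraction of 1.67 to 1.74, 2882 to 2942 genes changed against both other groups, and 10 to 13, 8 to 11 and 8 to 13 called lists. Replicate numbers did not pair the arrays: 1 of 9 same-number pairs had a correlation of deviations over 0.1 (range -0.048 to 0.257), and 2 arrays matched their own number best. With the replicate number as a block the calls were 320, 3498 and 3797, the F test gave 8799 genes, and the histone list of PR48 against K had adjusted p = 0.0511. Of 406 named results, 403 stayed on their side of the thresholds under median centring, 402 under repeated quantile normalisation and 406 under the block and under trended moderation. Genes near background limit the folds of low values such as LYZ in K.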

Other observations

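The tests of whole chromosomes in R48 against K and the subtractions of the PR48 share were chosen only after the result was seen. Growth factor receptors went both ways in the arrays labelled PR48, where 8 of 26 measured receptors were higher than in K and 8 were lower. FLT3 (5.51) and the interleukin 6 receptor IL6R (3.54) led the rises, while the shared cytokine receptor chain IL2RG (-3.36) and the receptor kinase MERTK (-3.26) led the falls, and the list was not called (camera adjusted p = 0.984). Of 26 genes that report ERK signalling, 4 were higher and 6 lower. FOS stood at 3.58 against K, while the feedback inhibitors SPRY2 (-2.44), SPRED1 (-2.09) and DUSP6 (-2.09) were lower. In the BCL2 family the survival gene BCL2 (2.62) rose together with the death genes BMF (0.97) and BAX (0.92), and BNIP3 (-2.22) and BCL2L1 (-0.66) fell. RUNX1T1 was lower by 3.85 log2 units in the same arrays (-3.85).

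In R48 against K, lists of other blood cells changed in few members. The azurophil granule genes ELANE (-0.85) and PRSS57 (-0.61) fell while LYZ rose. Among stem and progenitor genes MEIS1 (1.68) and NPR3 (1.56) rose and BAALC (-0.85) fell. With the PR48 share subtracted MEIS1 stood at 0.69 and NPR3 at 1.62, and with its upper quartile of 6.3%, close to the 6.02% that MEIS1 alone would need, they stood at -0.14 and 1.65. XK (-0.86) was the 1 erythroid gene called, IGLL1 (-0.66) the 1 B cell gene, and 0 of 29 T and NK cell genes and 0 of 26 megakaryocyte genes were called. Of 26 ERK output genes 0 were called between R48 and K (camera adjusted p = 0.241).

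Whole chromosomes shifted in R48 against K by small amounts, over 9194 genes above the median level. Chromosome 14 had a median of -0.16 with 87.7% of 285 genes lower, chromosome 20 -0.15 with 83.1% lower, chromosome 7 -0.12 with 79.9% lower and chromosome 18 0.16 with 82.9% higher. The PR48 share found in the R48 arrays does not account for these shifts, since the spread of the medians after its subtraction was 1.014 times that before. A change of chromosome dosage in the R48 cells was not decided: on these 4 chromosomes 43 of 43 runs of 25 neighbouring genes (100%) lay on the chromosome's side of 0, but so did at least 97.7% of runs in each of 1000 shuffles of the genes within their chromosome, so the runs do not bear on it and it stays open. In the arrays labelled PR48 the medians against K were -0.04 on chromosome 14 and 0.01 on chromosome 20, and -0.27 on chromosome 7 and 0.10 on chromosome 18.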
